A study of Homo sapiens with 36 samples.

How the data were processed

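The deposited table holds raw read counts per gene symbol for 36 libraries, 24 from 6 primary tumour samples labelled as CD4+ T cells and 12 from the lymphoma lines SeAx, HH and Hut78, each culture under 4 treatments. Per the labels' protocols, cells were treated for 24 h at doses equal to the 48-h IC50, RNA was isolated with TRIzol and RNeasy columns, and stranded libraries were made after ribosomal RNA depletion and sequenced as 100-base paired reads to a stated target depth. Per the same protocols, primary cells grew in human serum with IL-2 and IL-7 and were stimulated for 48 h before treatment, while lines grew in bovine serum and no stimulation of them is named. Medium, serum and stimulation therefore differ between primary cells and lines together with the kind of cell. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17, aligned to GRCh38 with STAR 2.5, and counted with featureCounts of the Subread package. The annotation and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes, and genes with near-identical copies, are uncertain. The values are whole numbers and were used as deposited. The table has 25559 symbols and no mitochondrially encoded genes. Of the symbols, 22424 were current or could be matched to 1 current symbol, and 3196, which include some of these, were left out of naming, among them X-inactivation and Y-linked genes and the gene segments of T-cell receptors and immunoglobulins.

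Genes were tested with edgeR 4.0.16 (R 4.3.3), using TMM scaling, its filter on low counts, robust quasi-likelihood fits and a Benjamini-Hochberg adjusted p of 0.05. Primary samples (15144 genes tested, 15 residual degrees of freedom) and lines (13849 genes, 6 residual degrees of freedom) were fitted apart, each with culture as a block. Differences between lines and primary samples came from a fit of all 36 libraries (16357 genes). The common biological coefficient of variation was 0.172 in primary samples and 0.135 in lines. Within each kind the comparisons were each treatment against vehicle, the combination against each single drug, and the interaction of the drugs, called non-additivity, which is 0 where log2 effects add up. A standard error is the absolute log2 fold change divided by the square root of the F statistic. The design, the alternatives and the gene lists were fixed before the data were examined. Labels name the culture of each library, and the pairing was checked on deviations from treatment means, whose lowest correlation within a culture was 0.592 in primary samples and 0.128 in lines. By expression of 2000 genes, 33 of 36 libraries lay nearest to a library of their own culture. No pair of libraries from a culture was a copy of the other (lowest chi-square per degree of freedom 2.81).

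Gene lists were tested with camera of limma 3.58.1, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with p-values adjusted over the lists tested in a comparison. There were 37 lists, 31 of pathways and 6 of markers of other cell types (B cells, monocytes and macrophages, CD8 T and NK cells, granulocytes, erythroid cells and platelets, keratinocytes and fibroblasts). Of their 1082 entries 1067 were in the table, and 36 lists had at least 3 tested members in some fit. Of 156 list calls over all comparisons, 16 held with an estimated correlation. Counts of called members are given over all genes tested and adjusted over the list alone.

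Genes were eligible for naming by a rule fixed beforehand. They were the 6 highest and 6 lowest genes of each comparison with vehicle, or 5 of other comparisons, among called genes with a mean of at least 3 log2 CPM and the same sign in every culture (without the sign condition for lines minus primary samples). The rule also took HDAC1, HDAC2, HDAC3, CDKN1A, MDM2, MYC, BCL2 and ABCB1, and up to 4 members of each list that passed camera or had at least 1 in 3 of its members called. The rule gave 1276 gene results, of which the text prints 241. These 241 were picked after their values were seen, with preference for genes whose call held under the alternatives. The effect of the alternatives on the others is given in the closing section. Some results that the rule names are not reported here. Positions are those of GENCODE release 29 on GRCh38.

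Alternatives fixed beforehand were DESeq2's size factors or library sizes in place of TMM, no filter on low counts or a filter of 1 CPM, DESeq2 1.42.0 and limma-voom in place of edgeR, no block for culture, a fit of all 36 libraries, the 50 most abundant genes left out, counts thinned to the smallest library (1841066 counts in lines), a log2 fold change beyond 1, and each culture left out in turn. Leaving out the romidepsin libraries of SeAx and primary replicate 6 was added after the data had been seen. Total counts were compared between treatments and vehicle with exact sign-flip tests over cultures. For comparisons that share vehicle libraries, 20 simulations of unchanged groups gave the correlation and covariance due to sharing alone. Each test was also run on up to 100 splits of the libraries, the real one included.

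The fits were tested on simulated counts made from the fitted means, dispersions and library sizes, with 200 genes changed in the combination. For the combination against vehicle at 2-fold, 77.6% of planted genes were recovered in primary samples (15144 genes) and 77.6% in lines (13849 genes), and at 1.5-fold 44.8% and 29.9%. For the interaction at 2-fold, 59.7% were recovered in primary samples and 44.8% in lines. For the difference of the combination effect between lines and primary samples (16357 genes) it was 37.3%. Unplanted calls numbered 6 in primary samples and 16 in lines for the combination against vehicle. They numbered 2 and 9 for the interaction and 2 for the difference. In lines both exceeded the threshold's share of calls. Either correlation called a planted list of 101 genes and no other. Genes were drawn independently, so the absence of other list calls does not cover lists of correlated genes. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 made tables and figures.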

Results

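RNA was sequenced from 3 established cutaneous T-cell lymphoma lines, SeAx, HH and Hut78, and from cells of 6 primary tumour samples labelled as CD4+ T cells. Each of the 9 cultures was divided over 4 treatments for 24 h, namely vehicle (DMSO), romidepsin, mechlorethamine and the combination of both drugs, which gave 36 libraries with 1 library per culture and treatment. Doses equalled the 48-h IC50 of each drug. Romidepsin inhibits class I histone deacetylases, and mechlorethamine is a nitrogen mustard that alkylates DNA and crosslinks its strands. The primary cells had been stimulated for 48 h through CD3 and CD28 before treatment. Counts were available for 25559 gene symbols. Total counts ran from 4382479 to 18649631 in the 24 primary libraries and from 1841066 to 8746244 in the 12 line libraries. Counts of the combination libraries of the lines were lower than those of vehicle in 3 of 3 lines, with a mean log2 ratio of -1.498 (exact two-sided sign-flip p = 0.25, the smallest that 3 pairs allow; adjusted p = 0.429 over 24 such tests). The same libraries held 14.04% ± 5.94 (SD, n = 3) of their counts in 5 structural RNAs, RN7SK, RN7SL1, RN7SL2, RMRP and RPPH1, against 5.31% ± 0.739 with vehicle, a measure chosen after the data had been seen. With romidepsin and mechlorethamine the lines had 7.99% ± 1.65 and 6.73% ± 1.35. In primary samples the shares were 6.38% ± 0.799 with the combination, 6.43% ± 1.27 with romidepsin, 7.26% ± 1.63 with mechlorethamine and 6.00% ± 1.48 with vehicle (SD, n = 6). The romidepsin libraries of SeAx and of primary replicate 6 stood apart in having counts for 253 and 162 of 372 olfactory receptor genes, receptors of the nasal epithelium. That number depends on depth, and the library of replicate 6 was the deepest of all. By summed CPM of these genes it stood at 25.26, below the romidepsin library of primary replicate 4 at 56.38. SeAx also had counts for 113 of them with vehicle and 138 with mechlorethamine. Counts without the romidepsin libraries of SeAx and primary replicate 6 stand beside the results they moved.

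The first question was what romidepsin alone did in the primary cells. Largest and lowest, here and below, mean among called genes with a mean of at least 3 log2 CPM and the same sign in every culture. Among the largest increases were CAVIN1 (listed as PTRF), a coat protein of caveolae, at a log2 fold change of 3.68 ± 0.37 (SE, n = 6 cultures; adjusted p = 3.13e-06), POU4F1, a neuronal transcription factor, at 3.60 ± 0.50, and DLL1, a Notch ligand, at 3.06 ± 0.30. CKB, the brain-type creatine kinase, and CGN, a tight junction protein, stood at 2.73 ± 0.41 and 2.58 ± 0.33. Among the largest decreases were SLC6A9, a glycine transporter, at -1.72 ± 0.25, DPEP2 at -1.50 ± 0.28, FOXP3, the lineage factor of regulatory T cells, at -1.45 ± 0.22, LGALS9, a galectin, at -1.44 ± 0.27, and ADI1 at -1.38 ± 0.17. Each of these genes moved the same way in all 6 cultures. In all, 3605 of 15144 tested genes passed an adjusted p of 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment), 1804 higher and 1801 lower, and 681 of the higher against 83 of the lower genes moved by more than 1 on the log2 scale. Without replicate 2 the count was 2035. Library sizes as the only scaling gave 2048 higher and 1534 lower, and no filter on low counts 1518 and 1780.

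Tested genes of neurons rose together with romidepsin in primary cells. Of the list's 50 genes in the table, 31 passed the filter on low counts here. That filter keeps a gene silent with vehicle only through treated libraries. Counts, medians and camera tests of this list, here and below, therefore lean towards a rise. Of 31 tested neuronal genes, 16 were higher, 0 lower and 15 not called (18 higher adjusted over the list alone), with a median log2 change of 0.96 and a camera adjusted p of 7.15e-08 (adjusted p = 0.0363 with an estimated correlation). KIF1A, a motor of axonal transport, stood at 3.67 ± 0.48, MAPT, which encodes tau, at 1.59 ± 0.28, and the synaptic proteins STX1A and SYT11 at 1.23 ± 0.23 and 1.01 ± 0.14. Without the romidepsin library of replicate 6, in which olfactory receptor genes had counts, the median over the 30 members tested with and without it went from 0.99 to 0.83, 13 of 31 members were higher, and the list no longer passed with an estimated correlation (camera adjusted p = 9.01e-08, adjusted p = 0.0694 with an estimated correlation). Among the fixed genes, HDAC3 rose by 0.60 ± 0.09 and ABCB1, the drug efflux pump P-glycoprotein, by 1.23 ± 0.24, while MYC fell by 0.65 ± 0.14 on the log2 scale. CDKN1A, the cyclin-dependent kinase inhibitor p21, was higher by 0.70 ± 0.18 (5 of 6 cultures; adjusted p = 0.00952, and 0.0695 without replicate 2). HDAC2, MDM2 and BCL2 did not pass the test (0.19 ± 0.09, -0.12 ± 0.20 and -0.12 ± 0.09). The linker histone H1-10 (listed as H1FX) and the histone H2AJ (listed as H2AFJ) rose by 1.01 ± 0.14 and 1.08 ± 0.18.

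Interferon-stimulated genes, T-cell receptor signalling, acetyltransferases with bromodomain proteins, and MYC targets passed as lower lists with romidepsin in primary cells, at the preset correlation only. Of 40 interferon-stimulated genes, 17 were lower, 2 higher and 21 not called (20 lower and 2 higher adjusted over the list alone; median -0.38, and -0.25 without replicate 2). IRF9, a subunit of the interferon-activated factor ISGF3, stood at -0.94 ± 0.15, and IFI35 at -0.85 ± 0.15, whereas HERC5, an ISG15 ligase, was higher at 0.87 ± 0.13. Of 39 genes of T-cell receptor signalling, 16 were lower, 1 higher and 22 not called (17 lower and 1 higher adjusted over the list alone). CD3E, a chain of the receptor complex, stood at -0.73 ± 0.13 and LAT, its adaptor, at -0.68 ± 0.13. Of 23 acetyltransferases and bromodomain proteins, 13 were lower and 2 higher (also adjusted over the list alone). CREBBP stood at -0.85 ± 0.15, KAT6B at -0.69 ± 0.12 and KAT5 at -0.60 ± 0.09. Of 50 MYC targets of ribosome biogenesis, 15 were lower, 0 higher and 35 not called (18 lower adjusted over the list alone). SRM, spermidine synthase, stood at -0.76 ± 0.13 and CAD, which starts pyrimidine synthesis, at -0.68 ± 0.10. The camera adjusted p-values of these 4 lists were 4.06e-05, 0.000509, 4.06e-05 and 6.81e-06. None held with an estimated correlation, at adjusted p = 0.966, 0.966, 0.194 and 0.966 with an estimated correlation. Genes of the p53 pathway moved both ways, 8 of 40 higher, as BTG2 at 0.46 ± 0.10, and 7 lower, as the death receptor FAS at -0.73 ± 0.15, with the same counts adjusted over the list alone.

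Mechlorethamine alone raised a compact group of p53 targets in primary cells. Among the largest increases were PHLDA3, an inhibitor of AKT, at 2.26 ± 0.18 (SE, n = 6 cultures, adjusted p = 1.47e-08), and FDXR, ferredoxin reductase, at 2.05 ± 0.16. Also among them were TNFSF4, the OX40 ligand, at 1.99 ± 0.26, the receptor EDA2R at 1.96 ± 0.25, and TNFRSF10D, a decoy receptor for TRAIL, at 1.54 ± 0.16. Each rose in 6 of 6 cultures. Of 40 p53 targets, 25 were higher, 0 lower and 15 not called (37 higher adjusted over the list alone; median 0.85, camera adjusted p = 4.72e-125, and adjusted p = 4.48e-07 with an estimated correlation). CDKN1A rose by 1.41 ± 0.18, RPS27L by 1.09 ± 0.10 and ZMAT3 by 1.001 ± 0.10. MDM2, a ubiquitin ligase, was higher by 1.04 ± 0.20 (adjusted p = 0.0229, but 0.0709, 0.144 and 0.118 without replicates 1, 2 and 4 and 0.0631 with no filter on low counts). FDXR lies on chromosome 17 (GRCh38, 74862497 to 74873031), PHLDA3 on chromosome 1 (201464383 to 201469237), CDKN1A on chromosome 6 (36676460 to 36687339) and MDM2 on chromosome 12 (68808176 to 68850686). Among 21 pro-apoptotic genes and death receptors, BBC3 (PUMA), BAX and TNFRSF10B rose by 1.38 ± 0.18, 0.95 ± 0.10 and 0.80 ± 0.10, and the other 18 were not called (camera adjusted p = 1.74e-06, and adjusted p = 0.000929 with an estimated correlation). In all 99 genes passed, 70 higher and 29 lower. That majority turned with DESeq2 (240 genes, 115 higher and 125 lower), limma-voom (248, 104 higher and 144 lower), a fit of all 36 libraries (170, 79 higher and 91 lower) and without replicate 5 (150, 69 higher and 81 lower). Without replicates 2, 3 and 4 the higher genes numbered 49, 38 and 47 and the lower ones 10, 0 and 2. With library sizes as the only scaling, 65 were higher and 47 lower.

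Lists of cell division genes were lower with mechlorethamine in primary cells at the preset correlation only, with few members called over all genes. Of 55 genes of G2 and mitosis, 9 were lower, 0 higher and 46 not called over all genes tested, and 50 were lower adjusted over the list alone (median -0.79, and -0.47 without replicate 6; camera adjusted p = 3.64e-43, adjusted p = 0.124 with an estimated correlation). In the same libraries the share of structural RNA was higher than with vehicle in 5 of 6 cultures (mean difference 1.26 ± 1.12 percentage points, SD; exact two-sided sign-flip test, adjusted p = 0.214), and that of RN7SK alone in 6 of 6 (0.776 ± 0.533; exact sign-flip p = 0.0312, adjusted p = 0.188). CDC20, an activator of the anaphase-promoting complex, stood at -1.63 ± 0.32 (adjusted p = 0.0174) and KIF23, a kinesin of cytokinesis, at -1.21 ± 0.23 (adjusted p = 0.00819). CDC20 did not pass without replicates 2, 3 or 4 (adjusted p = 0.0888, 0.189 and 0.1) or with no filter on low counts (adjusted p = 0.057), and KIF23 did not pass without replicates 2 or 3 (adjusted p = 0.0654 and 0.135). Of 50 S-phase genes, 1 was lower over all genes tested and 28 adjusted over the list alone (median -0.41, and -0.25 without replicate 6; camera adjusted p = 3.42e-22, adjusted p = 0.146 with an estimated correlation), and of 45 replication-dependent core histones 0 were called (edgeR, over all genes tested) and 30 were lower adjusted over the list alone (median -0.67; camera adjusted p = 1.93e-24, adjusted p = 0.151 with an estimated correlation). Of 72 ribosomal protein genes, 3 were higher, 0 lower and 69 not called (25 higher adjusted over the list alone; median 0.15, camera adjusted p = 2.66e-21, adjusted p = 0.164 with an estimated correlation). RPS19 stood at 0.52 ± 0.07. The markers of CD8 T and NK cells were lower as a list (8 genes, none called; median -0.52, and -0.25, -0.93 and -0.34 without replicates 3, 5 and 6; camera adjusted p = 0.00736, but 0.052 and 0.0966 without replicates 3 and 6; adjusted p = 0.136 with an estimated correlation), as were 3 granulocyte markers (median -1.32, and -0.63 and -0.38 without replicates 3 and 4; camera adjusted p = 0.017, but 0.0897 without replicate 4; adjusted p = 0.136 with an estimated correlation). MYC, HDAC2 and HDAC3 did not pass the test (-0.33 ± 0.14, -0.12 ± 0.09 and 0.06 ± 0.10).

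The combination in primary cells joined the leading changes of either drug. CAVIN1 stood at 3.94 ± 0.37 (SE, n = 6 cultures; adjusted p = 2.06e-07), POU4F1 at 3.83 ± 0.50, DLL1 at 3.24 ± 0.30 and LRP1, an endocytic receptor, at 2.93 ± 0.32. The lowest values were in CCNB1, the mitotic cyclin B1, at -2.18 ± 0.45, CDC20 at -2.04 ± 0.33, PLK1, a mitotic kinase, at -1.97 ± 0.33, SLC6A9 at -1.91 ± 0.26, ADI1 at -1.84 ± 0.17 and POGLUT3 (listed as KDELC2) at -1.75 ± 0.17. In all 5220 genes passed, 2549 higher and 2671 lower, and the majority turned with library sizes only (2895 higher and 2205 lower), DESeq2 (2837 and 2715) and DESeq2's size factors (2620 and 2557). Of 40 p53 targets, 32 were higher, 1 lower and 7 not called (33 higher and 1 lower adjusted over the list alone; median 0.75, camera adjusted p = 4.13e-21, and adjusted p = 0.0137 with an estimated correlation). FDXR stood at 1.79 ± 0.16, CDKN1A at 1.68 ± 0.18, ZMAT3 at 1.30 ± 0.10, SESN1 at 1.20 ± 0.13 and MDM2 at 1.02 ± 0.20. BMF, a BH3-only protein, and BBC3 rose by 1.58 ± 0.19 and 1.56 ± 0.18. Of 31 neuronal genes, 21 were higher and 10 not called (22 higher and 1 lower adjusted over the list alone; median 1.22, camera adjusted p = 6.24e-07, and adjusted p = 0.0434 with an estimated correlation). KIF1A stood at 3.78 ± 0.48.

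Lists of the cell cycle, ribosome biogenesis, repair and T-cell signalling were lower with the combination in primary cells, at the preset correlation only. Of 55 genes of G2 and mitosis, 53 were lower, 1 higher and 1 not called, with the same counts adjusted over the list alone, including GTSE1 at -1.61 ± 0.23 and UBE2C at -1.42 ± 0.23 (median -1.23). Of 50 S-phase genes, 42 were lower, 0 higher and 8 not called (45 lower adjusted over the list alone; median -0.74). The replicative helicase subunits MCM2 and MCM5 stood at -1.23 ± 0.17 and -1.18 ± 0.17. Of 50 MYC targets of ribosome biogenesis, 31 were lower, 0 higher and 19 not called (34 lower adjusted over the list alone; median -0.37). SRM stood at -1.13 ± 0.13 and UTP20 at -1.10 ± 0.14, and MYC itself fell by 0.91 ± 0.14. Of 37 genes of crosslink and homologous recombination repair, 17 were lower, 1 higher and 19 not called (19 lower and 2 higher adjusted over the list alone; median -0.38). BRCA1 stood at -1.12 ± 0.19. Camera adjusted p-values were 4.13e-21, 7.56e-15, 1.52e-11 and 0.00105, against adjusted p = 0.323, 0.335, 0.323 and 0.385 with an estimated correlation. Of 39 genes of T-cell receptor signalling, 19 were lower, 3 higher and 17 not called (21 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.000998, adjusted p = 0.634 with an estimated correlation), while the cytokines TNF and LTA rose by 1.01 ± 0.15 and 0.84 ± 0.10 and the activation marker CD69 by 1.44 ± 0.22.

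Adding mechlorethamine to romidepsin in primary cells raised p53 targets and lowered genes of G2 and mitosis as lists. EDA2R stood 1.85 ± 0.26 above romidepsin alone (SE, n = 6 cultures; adjusted p = 0.000143), PHLDA3 1.796 ± 0.19, FDXR 1.62 ± 0.16 and BBC3 1.35 ± 0.18. Of 40 p53 targets, 22 were higher, 0 lower and 18 not called (34 higher adjusted over the list alone; median 0.76, camera adjusted p = 2.09e-101, and adjusted p = 1.36e-06 with an estimated correlation), and AEN, ZMAT3 and BAX rose by 1.10 ± 0.12, 0.98 ± 0.10 and 0.89 ± 0.10. Of 55 genes of G2 and mitosis, 13 were lower, 0 higher and 42 not called (50 lower adjusted over the list alone; median -0.94, camera adjusted p = 4.68e-59, and adjusted p = 0.0462 with an estimated correlation). DLGAP5, a spindle protein, stood at -1.35 ± 0.25 (adjusted p = 0.0141, but 0.104 and 0.134 without replicates 2 and 3). The markers of CD8 T and NK cells were lower as a list (8 genes, none called, 1 lower adjusted over the list alone; median -0.50, and -0.32 and -0.26 without replicates 3 and 6; camera adjusted p = 0.037, but 0.163 and 0.356 without replicates 5 and 6 and 0.243 without the romidepsin library of replicate 6; adjusted p = 0.271 with an estimated correlation). In all 81 genes passed, 53 higher and 28 lower. That majority turned with DESeq2 (186 genes, 83 higher and 103 lower), limma-voom (152, 61 higher and 91 lower) and a fit of all 36 libraries (151, 62 higher and 89 lower). The count was 43, 23, 26 and 23 without replicates 1, 2, 3 and 4, and 29 without the romidepsin library of replicate 6.

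Adding romidepsin to mechlorethamine in primary cells moved far more genes. CAVIN1 stood 4.54 ± 0.38 above mechlorethamine alone (SE, n = 6 cultures; adjusted p = 1.9e-07), POU4F1 3.44 ± 0.49, CKB 3.40 ± 0.43 and MCAM, an adhesion molecule, 3.09 ± 0.34, while POGLUT3, SLC6A9 and ADI1 stood at -1.81 ± 0.17, -1.76 ± 0.26 and -1.71 ± 0.17. Of 31 neuronal genes, 17 were higher, 0 lower and 14 not called (21 higher adjusted over the list alone; median 1.24, camera adjusted p = 1.48e-07, and adjusted p = 0.0497 with an estimated correlation). KIF1A stood at 4.14 ± 0.50 and STX1A at 1.41 ± 0.23. Of 40 interferon-stimulated genes, 21 were lower, 1 higher and 18 not called (24 lower and 2 higher adjusted over the list alone; median -0.56, and -0.35 without replicate 2; camera adjusted p = 1.48e-07, adjusted p = 0.833 with an estimated correlation). IRF9 stood at -1.004 ± 0.15. In all 4319 genes passed, 2176 higher and 2143 lower, against 2802 genes without replicate 2. When libraries were scaled by size alone, the split was 2750 higher and 1515 lower.

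Departure from the sum of the drugs' log2 effects was tested as an interaction. In primary cells edgeR, DESeq2 and limma-voom called 0 of 15144 genes. Only 339 had an unadjusted edgeR p under 0.05, fewer than by chance, so additivity stays open. Ribosomal protein genes as a list lay slightly below the sum (72 genes, none called, median -0.15, and -0.23, -0.08 and -0.10 without replicates 4, 5 and 6; camera adjusted p = 8.21e-15, adjusted p = 0.994 with an estimated correlation).

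In the lines, romidepsin alone raised a different set of leading genes. PLK2, a stress-responsive polo-like kinase, stood at 4.75 ± 0.33 (SE, n = 3 lines; adjusted p = 3.25e-11), ADM, the vasodilator adrenomedullin, at 4.65 ± 0.49, CEBPA, a myeloid transcription factor, at 4.37 ± 0.41, DLX2, a homeobox factor of the forebrain, at 4.30 ± 0.41, RASD1 at 4.28 ± 0.46 and DLL4, a Notch ligand, at 4.04 ± 0.34. LTB, lymphotoxin beta, was lowest at -3.05 ± 0.25, and among the other largest decreases were the cytokine OSM at -2.59 ± 0.31, CMAHP at -2.50 ± 0.16, TFEC at -2.11 ± 0.25 and CSF2RB, the shared receptor chain of IL-3, IL-5 and GM-CSF, at -2.10 ± 0.23, all in 3 of 3 lines. ABCB1 rose by 4.14 ± 0.53 (adjusted p = 1.21e-06). ABCB1 lies on chromosome 7 (87503633 to 87713323). CDKN1A was higher by 2.58 ± 0.59 (adjusted p = 0.0141, and 0.158 without SeAx), and MYC was lower at -0.71 ± 0.20 (adjusted p = 0.0186, and 0.0594 in counts thinned to the smallest library). In all 4527 of 13849 tested genes passed, 2316 higher and 2211 lower, against 2904 and 2542 genes without SeAx and Hut78 and 2828 in counts thinned to the smallest library. With library sizes as the only scaling the split was 2713 higher and 1591 lower, and the majority turned in a fit of all 36 libraries (1815 and 2351), with no filter on low counts (2214 and 2440) and without HH (2567 and 2635).

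At the preset correlation only, lists of the stress response and of neurons were higher with romidepsin in the lines, and MYC targets were lower. Of 34 genes of the unfolded protein and integrated stress response, 13 were higher, 2 lower and 19 not called (14 higher and 2 lower adjusted over the list alone; median 0.26, camera adjusted p = 7.09e-05, adjusted p = 0.138 with an estimated correlation), led by the transcription factor ATF3 at 3.24 ± 0.18, CHAC1, which degrades glutathione, at 2.74 ± 0.22 and PPP1R15A (GADD34), which restarts translation, at 1.33 ± 0.14. Of 29 neuronal genes, 17 were higher, 0 lower and 12 not called (19 higher adjusted over the list alone; median 1.496, and 1.476 without the romidepsin library of SeAx; camera adjusted p = 1.07e-07, adjusted p = 0.138 with an estimated correlation). The secretory granule proteins SCG2 and CHGB stood at 3.67 ± 0.49 and 3.02 ± 0.33 and SYP, synaptophysin, at 2.49 ± 0.27. Of 50 MYC targets, 36 were lower, 0 higher and 14 not called (42 lower adjusted over the list alone; median -0.61, camera adjusted p = 1.73e-15, adjusted p = 0.241 with an estimated correlation). UTP20 and MRTO4 stood at -1.10 ± 0.13 and -1.12 ± 0.15. Among genes of cell survival, BCL2L1 (BCL-XL) stood at -1.42 ± 0.15 and FAS at -1.95 ± 0.18, while TNFRSF10B, a TRAIL receptor, and BTG2 rose by 1.33 ± 0.17 and 1.93 ± 0.23. The T-cell factors BACH2, AHR and FOXO1 rose by 2.42 ± 0.28, 1.48 ± 0.14 and 1.23 ± 0.17. Of 4 monocyte and macrophage markers 2 were higher (3 adjusted over the list alone; camera adjusted p = 0.0409, but 0.0553 and 0.129 without SeAx and HH, and 0.0932 without the romidepsin library of SeAx; adjusted p = 0.415 with an estimated correlation). The receptor CLEC7A stood at 3.03 ± 0.38.

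Mechlorethamine alone in the lines gave a stress response as its leading change. PLK2 rose by 3.54 ± 0.37 (SE, n = 3 lines; adjusted p = 2.75e-07), ATF3 by 3.50 ± 0.18, DLX2 by 3.29 ± 0.45, RASD1 by 3.22 ± 0.51, SNAI1, a repressor of epithelial genes, by 3.19 ± 0.29 and IER5L by 2.95 ± 0.23. The lowest were PSRC1, a spindle protein, at -1.95 ± 0.24, OSM at -1.85 ± 0.30, TFEC at -1.75 ± 0.25, LTB at -1.71 ± 0.23 and the chemokine receptor CCR2 at -1.59 ± 0.21. Of 34 stress response genes, 16 were higher, 1 lower and 17 not called, with the same counts adjusted over the list alone (median 0.56, camera adjusted p = 2e-18, and adjusted p = 0.00367 with an estimated correlation). PPP1R15A stood at 2.27 ± 0.14 and DDIT3 (CHOP), which promotes apoptosis under stress, at 1.81 ± 0.15. Of 36 p53 targets, 11 were higher, 0 lower and 25 not called (16 higher and 1 lower adjusted over the list alone; median 0.31, camera adjusted p = 1.96e-06, adjusted p = 0.0752 with an estimated correlation). GADD45A stood at 1.53 ± 0.23, PLK3 at 1.24 ± 0.22 and TNFRSF10B at 1.19 ± 0.17. Effects on the p53 targets FDXR, RPS27L and BAX were lower in the lines than in primary cells, as given below. CDKN1A did not pass the test over 3 lines (1.94 ± 0.60, adjusted p = 0.0814), but passed without HH or Hut78 (adjusted p = 0.00947 and 0.00647), with DESeq2 (adjusted p = 0.0107), in a fit of all 36 libraries (adjusted p = 0.00709) and in counts thinned to the smallest library (adjusted p = 0.0153). In all 1956 genes passed, 986 higher and 970 lower, against 828 and 791 without SeAx and Hut78. When libraries were scaled by size alone, the split was 1223 higher and 641 lower, and a fit of all 36 libraries gave 614 and 1082.

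With mechlorethamine in the lines, the lists of S phase and of crosslink repair were higher and those of mitosis, core histones and ribosomal proteins lower, at the preset correlation only. Of 50 S-phase genes, 27 were higher, 1 lower and 22 not called (29 higher and 2 lower adjusted over the list alone; median 0.40). E2F2, a transcription factor of S-phase genes, stood at 1.24 ± 0.14, the cyclin CCNE2 at 1.05 ± 0.13 and the polymerase subunit POLD3 at 1.02 ± 0.13. Of 37 genes of crosslink and homologous recombination repair, 11 were higher, 0 lower and 26 not called (13 higher adjusted over the list alone; median 0.22). The helicase BRIP1 stood at 0.97 ± 0.14 and REV3L, the translesion polymerase, at 0.77 ± 0.14. Of 55 genes of G2 and mitosis, 21 were lower, 1 higher and 33 not called (24 lower and 2 higher adjusted over the list alone; median -0.23, and -0.15 without SeAx). BUB1, a spindle checkpoint kinase, stood at -0.97 ± 0.14. Of 45 core histones, 26 were lower, 0 higher and 19 not called (30 lower and 1 higher adjusted over the list alone; median -0.45, and -0.26 without Hut78), and of 72 ribosomal protein genes 25 were lower, 0 higher and 47 not called (49 lower adjusted over the list alone; median -0.32). RPL7A stood at -0.53 ± 0.11. Camera adjusted p-values of these 5 lists were 1.83e-16, 5.04e-05, 1.89e-08, 1.07e-13 and 1.47e-13, and none held with an estimated correlation, at adjusted p = 0.0752, 0.217, 0.353, 0.471 and 0.471 with an estimated correlation. Copies of histone and ribosomal protein genes are near-identical and have pseudogenes, so counts of single members are uncertain. The NF-kB subunit REL rose by 1.26 ± 0.18 and the glycolytic enzymes HK1 and PGK1 stood at -0.92 ± 0.13 and -0.83 ± 0.12.

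In the lines, 7164 of 13849 genes changed with the combination, 3615 higher and 3549 lower, and 3212 moved by more than 1 on the log2 scale. Library sizes as the only scaling gave 4003 higher and 3134 lower genes, and a fit of all 36 libraries 2968 and 3917. PLK2 stood at 6.94 ± 0.30 (SE, n = 3 lines; adjusted p = 4.8e-16), CEBPA at 6.68 ± 0.37, DLX2 at 6.16 ± 0.38, HAP1, a protein of neuronal transport, at 5.97 ± 0.32, DLL4 at 5.96 ± 0.32 and RASD1 at 5.88 ± 0.44. TFEC was lowest at -3.71 ± 0.30, followed by CCR2 at -3.51 ± 0.28, LTB at -3.34 ± 0.29, HTR2B, a serotonin receptor, at -3.11 ± 0.22, WNT8B at -2.82 ± 0.34 and ABCA12, a lipid transporter, at -2.78 ± 0.33. ABCB1 rose by 4.65 ± 0.54, while HDAC1, BCL2 and MYC stood at -0.91 ± 0.13, -1.29 ± 0.19 and -1.04 ± 0.21. CDKN1A was higher by 3.45 ± 0.59 (adjusted p = 0.00214, and 0.0564 without SeAx). Of 34 stress response genes, 21 were higher, 3 lower and 10 not called (21 higher and 4 lower adjusted over the list alone; median 0.65, camera adjusted p = 4.81e-08, and adjusted p = 0.0357 with an estimated correlation). ATF3 stood at 5.22 ± 0.19, CHAC1 at 3.92 ± 0.23 and DDIT3 at 2.67 ± 0.15. ATF3 lies on chromosome 1 (212565334 to 212620777). BBC3 and GADD45A rose by 3.69 ± 0.33 and 2.96 ± 0.23, and of the survival genes BCL2L1 fell by 1.801 ± 0.17 while MCL1 rose by 1.09 ± 0.13.

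Ribosomal protein genes fell nearly as a block with the combination in the lines. Of 72 such genes, 69 were lower, 0 higher and 3 not called, also adjusted over the list alone (median -0.65). RPL23, RPL7A and RPS7 stood at -1.01 ± 0.12, -0.97 ± 0.11 and -0.93 ± 0.11, and their share of all counts was 3.73% ± 0.293 (SD, n = 3) against 5.71% ± 0.533 with vehicle. The share of structural RNA was higher in these libraries, as given above. Of 50 MYC targets, 32 were lower, 2 higher and 16 not called (32 lower and 2 higher adjusted over the list alone; median -0.62). HSPD1, DKC1 and NPM1 stood at -1.49 ± 0.12, -1.26 ± 0.12 and -1.16 ± 0.11. Of 37 genes of T-cell receptor signalling, 19 were lower, 2 higher and 16 not called (19 lower and 2 higher adjusted over the list alone; median -0.85). The kinase LCK stood at -1.94 ± 0.19, the receptor chain CD247 at -1.74 ± 0.17 and the phosphatase PTPRC (CD45) at -1.54 ± 0.13. Of 29 neuronal genes, 19 were higher and 2 lower (19 and 2 adjusted over the list alone; median 2.02). VGF and CHGB, cargo of secretory granules, stood at 4.44 ± 0.33 and 4.09 ± 0.33. Camera adjusted p-values were 2.48e-15, 3.54e-07, 4.54e-05 and 1.18e-06, against adjusted p = 0.497, 0.497, 0.241 and 0.241 with an estimated correlation.

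Relative to romidepsin alone, the combination in the lines changed 3407 genes, 1626 higher and 1781 lower, against 1766 and 1661 without SeAx and Hut78, and the majority turned in 5 of 13 other settings. VGF stood 3.12 ± 0.30 higher (SE, n = 3 lines; adjusted p = 9.61e-08), CEBPA 2.32 ± 0.25, and PLK2 2.20 ± 0.20, while ABCA12, PLAC4 and APOL4 stood at -2.42 ± 0.34, -2.12 ± 0.29 and -1.72 ± 0.20. Of 72 ribosomal protein genes 61 were lower and 0 higher (68 lower adjusted over the list alone; camera adjusted p = 1.08e-20, adjusted p = 0.506 with an estimated correlation). Of 34 stress response genes 14 were higher and 2 lower (14 and 3 adjusted over the list alone; camera adjusted p = 2.51e-06, adjusted p = 0.067 with an estimated correlation). ATF3 stood at 1.98 ± 0.15. Of 50 S-phase genes 22 were higher and 5 lower (26 and 5 adjusted over the list alone; camera adjusted p = 0.00013, adjusted p = 0.484 with an estimated correlation). E2F1 stood at 0.95 ± 0.13 and CDC6 at 0.83 ± 0.12.

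Relative to mechlorethamine alone, the combination in the lines changed 5628 genes, 2765 higher and 2863 lower, against 3369 without Hut78, and the majority turned in 8 of 13 other settings. ADM stood 5.19 ± 0.49 higher (SE, n = 3 lines; adjusted p = 6.9e-08), DLL4 4.55 ± 0.30, CEBPA 4.46 ± 0.32 and PLEKHH2 4.02 ± 0.28, while the calcium-binding protein RCN1, the collagen COL3A1 and the receptor GPR171 stood at -2.63 ± 0.30, -2.53 ± 0.31 and -2.16 ± 0.17. Of 45 core histones 35 were higher and 0 lower (36 higher adjusted over the list alone; median 0.55, camera adjusted p = 2.96e-08, adjusted p = 0.519 with an estimated correlation). The H4 gene HIST1H4L stood at 1.02 ± 0.13. Of 50 MYC targets 34 were lower and 0 higher (36 lower adjusted over the list alone; camera adjusted p = 6.37e-10, adjusted p = 0.321 with an estimated correlation). DKC1 stood at -1.32 ± 0.12.

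In the lines 13 genes departed from the sum of the single drugs, 6 above it and 7 below it, and 1408 had an unadjusted p under 0.05. ATF3 lay below the sum at -1.52 ± 0.24 (SE, n = 3 lines; adjusted p = 0.00366), although it rose with each drug and rose most with both. GPR171 and PDE4D, a cyclic AMP phosphodiesterase, lay below it at -1.71 ± 0.22 and -1.68 ± 0.26. Core histones as a list lay above the sum, with 1 of 45 members called and 36 adjusted over the list alone (median 0.65, camera adjusted p = 1.16e-38, adjusted p = 0.263 with an estimated correlation). DESeq2 called 59 genes (41 above and 18 below) and limma-voom 29. No filter on low counts gave 114 (72 above and 42 below), the count was 19, 135 and 7 without SeAx, HH and Hut78, and it was 5 without the romidepsin library of SeAx. DESeq2's size factors gave 14 higher and 7 lower, library sizes alone 1 and 7, and leaving out the 50 most abundant genes 12 and 7.

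The effects of each drug were then set against each other between lines and primary cells, as the effect in the lines minus that in the primary cells. With romidepsin 1122 of 16357 genes differed, 499 with a higher and 623 with a lower value in the lines. PLK2 stood 4.87 ± 0.79 higher (SE, n = 3 lines and 6 primary cultures; adjusted p = 0.000414) and LTB was lower in the lines at -2.76 ± 0.23. Of 27 T-helper lineage factors 8 had a higher and 2 a lower effect in the lines (10 and 3 adjusted over the list alone; adjusted p = 0.0313 with an estimated correlation; median 0.63, and 0.37 without Hut78). SATB1 stood at 2.04 ± 0.28, BACH2 at 2.00 ± 0.23 and TCF7 at 1.90 ± 0.26. Of 34 stress response genes 8 were higher and 0 lower (12 higher adjusted over the list alone; adjusted p = 0.00398 with an estimated correlation). CHAC1 stood at 3.06 ± 0.32 and ATF3 at 2.83 ± 0.26. Of 9 drug efflux transporters 2 were higher (4 adjusted over the list alone; adjusted p = 0.014 with an estimated correlation). ABCB1 stood at 2.90 ± 0.69 (adjusted p = 0.00948, but 0.0982 and 0.0599 without HH and Hut78, 0.0602 with limma-voom and 0.074 in thinned counts). The interferon gene STAT2 stood 1.02 ± 0.17 higher. The count was 498 and 437 without SeAx and Hut78, 746 without HH, 511 in thinned counts and 507 without the romidepsin libraries of SeAx and primary replicate 6. With library sizes as the only scaling the split was 593 higher and 321 lower, and without the 50 most abundant genes 522 and 417. The majority also turned without SeAx (275 higher and 223 lower), HH (382 and 364) and primary replicates 2 (429 and 399), 4 (494 and 412) and 5 (452 and 309), in thinned counts (295 and 216) and without the 2 romidepsin libraries (337 and 170). It turned too with DESeq2 (701 and 650), its size factors (521 and 453) and a filter of 1 CPM (534 and 431).

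With mechlorethamine 1096 genes differed between lines and primary cells, 426 higher and 670 lower in the lines. Of 34 stress response genes 14 had a higher effect in the lines and 0 a lower one (17 higher adjusted over the list alone; adjusted p = 0.000139 with an estimated correlation; median 0.59). ATF3 stood at 2.35 ± 0.26, TRIB3 at 1.98 ± 0.28 and PPP1R15A at 1.91 ± 0.17 (SE, n = 3 lines and 6 primary cultures). Of 40 p53 targets 11 had a lower effect in the lines and 0 a higher one (13 lower and 4 higher adjusted over the list alone; median -0.38, and -0.24 with library sizes as the only scaling; camera adjusted p = 6.8e-05, adjusted p = 0.174 with an estimated correlation). FDXR stood at -1.92 ± 0.29, RPS27L at -1.28 ± 0.20, CCNG1 at -1.27 ± 0.20 and BAX at -1.10 ± 0.19. Of 50 S-phase genes 26 had a higher effect in the lines and 0 a lower one (37 higher adjusted over the list alone; camera adjusted p = 2.28e-26, adjusted p = 0.132 with an estimated correlation). CHAF1B stood at 1.34 ± 0.24 and POLA1 at 1.02 ± 0.17. Of 72 ribosomal protein genes 59 were lower (69 adjusted over the list alone; camera adjusted p = 1.95e-43, adjusted p = 0.117 with an estimated correlation). RPS19 stood at -0.85 ± 0.13. The count was 455, 592 and 527 without SeAx, HH and Hut78 and 709 in thinned counts. When libraries were scaled by size alone, the median of all genes moved by 0.138, to 0.118, and the split was 758 higher and 288 lower. The majority also turned without primary replicates 4 (521 higher and 411 lower) and 5 (517 and 317), in thinned counts (372 and 337), with a filter of 1 CPM (580 and 422) and without the 2 romidepsin libraries that stood apart (542 and 379).

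With the combination 4398 genes differed, 1750 higher and 2648 lower in the lines, around a median of all genes of -0.11. PLK2, CEBPA and FOS, an early response factor, stood 5.44 ± 0.77, 5.21 ± 0.56 and 4.72 ± 0.54 higher in the lines (SE, n = 3 lines and 6 primary cultures). Of 34 stress response genes 19 had a higher effect and 0 a lower one (21 higher and 1 lower adjusted over the list alone; adjusted p = 0.000539 with an estimated correlation; median 0.75). CHAC1 stood at 3.96 ± 0.32 and ATF3 at 3.62 ± 0.26. Of 72 ribosomal protein genes 69 had a lower effect in the lines and 0 a higher one (70 lower adjusted over the list alone; median -0.85, camera adjusted p = 6.13e-45, adjusted p = 0.0851 with an estimated correlation). RPL23 stood at -1.49 ± 0.15 and RPL7A at -1.21 ± 0.12. Genes of T-cell receptor signalling were lower in the lines in 16 and higher in 2 of 39 (20 and 2 adjusted over the list alone; median -0.74, and -0.38 without HH; camera adjusted p = 0.000421, adjusted p = 0.448 with an estimated correlation). LCK stood at -1.58 ± 0.21. Of 50 S-phase genes 24 were higher and 4 lower (31 and 4 adjusted over the list alone; camera adjusted p = 2.77e-09, adjusted p = 0.448 with an estimated correlation). CDC6 stood at 1.84 ± 0.25. With library sizes as the only scaling the median of all genes moved by 0.122, to 0.016, and the split was 2164 higher and 1907 lower. It was 2048 and 1993 without primary replicate 4, 1933 and 1805 without primary replicate 5, 2055 and 1992 without the 2 romidepsin libraries that stood apart, 2154 and 2052 with a filter of 1 CPM and 2223 and 2209 with DESeq2.

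Effects in lines and primary cells, which share no libraries, were also compared gene by gene over the 13135 genes tested in both, a correlation across genes that are not independent replicates. With romidepsin Pearson's r was 0.588, and 854 genes were called higher in both against 258.3 expected for independent lists, 863 lower in both against 290.5, and 47 in opposite directions. With mechlorethamine r was 0.103, and 17 genes were higher in both against 4.57 expected and 10 lower in both against 2.08, while 5 went opposite ways. With the combination r was 0.541, 1304 genes were higher in both against 586.5 expected, 1491 lower in both against 686.3, and 309 went opposite ways.

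Comparisons against the same vehicle libraries share their chance values, so each is given beside simulated unchanged groups. In primary cells each is also given with its 2 effects taken from separate cultures, averaged over 20 splits, called split vehicle libraries below. Such a split also leaves fewer cultures per effect and no shared response of a culture, so a lower r need not come from the controls alone. In primary cells the covariance of the romidepsin and combination effects was 0.351 (r = 0.890), against 0.0377 (r = 0.497) for unchanged groups and 0.327 (r = 0.640) with split vehicle libraries. The mechlorethamine and combination effects had a covariance of 0.0817 (r = 0.364), against 0.0378 (r = 0.497, above the observed r) for unchanged groups and 0.045 (r = 0.128) with split vehicle libraries, and 60 of the 70 genes higher with mechlorethamine were higher with the combination against 11.8 expected for independent lists. The 2 single drugs had a covariance of 0.0432 (r = 0.217), against 0.038 (r = 0.502, above the observed r) for unchanged groups and 0.0132 (r = 0.0417) with split vehicle libraries. In primary cells 12 genes were higher with both single drugs against 8.34 expected, 5 lower with both against 3.45, and 9 went opposite ways. In the lines the cultures were too few to split, so part of any excess may come from the shared controls. Their covariances were 0.765 (r = 0.855) for romidepsin and combination, 0.359 (r = 0.618) for mechlorethamine and combination and 0.190 (r = 0.451) for the single drugs, against 0.0383 (r = 0.424), 0.0393 (r = 0.420) and 0.0382 (r = 0.461) for unchanged groups. In the lines 378 genes were higher with both single drugs against 164.9 expected for independent lists, 383 were lower with both against 154.9, and 117 went opposite ways. The overlaps of unchanged groups averaged between 0 and 0.15 genes over 20 simulations.

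Markers of other cell types were fixed as 6 lists to look for cells other than T cells. In primary cells the B-cell list did not pass with romidepsin (7 genes, 1 higher and 1 lower, median 0.29, camera adjusted p = 0.991), as did the lists of monocytes and macrophages (5 genes, none called, camera adjusted p = 0.847), CD8 T and NK cells (8 genes, none called, camera adjusted p = 0.991), granulocytes (3 genes, none called, camera adjusted p = 0.957), erythroid cells and platelets (5 genes, none called, camera adjusted p = 0.775) and keratinocytes and fibroblasts (4 genes, 1 higher and 1 lower, camera adjusted p = 0.586). With the combination against vehicle none of the 6 lists passed in primary cells, with camera adjusted p-values from 0.468 to 0.933. Against romidepsin alone the CD8 T and NK list was lower, as given above. Also given above, the CD8 T and NK and granulocyte lists were lower with mechlorethamine in primary cells. The monocyte and macrophage list was higher with romidepsin in the lines. In the lines the B-cell and granulocyte lists held too few expressed genes to be tested. The keratinocyte and fibroblast list had 4 of 8 members higher and 2 lower with romidepsin (camera adjusted p = 0.646), the CD8 T and NK list 1 higher and 2 lower (camera adjusted p = 0.404) and the erythroid and platelet list 1 of 3 higher (camera adjusted p = 0.468).

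**Figure D1:**
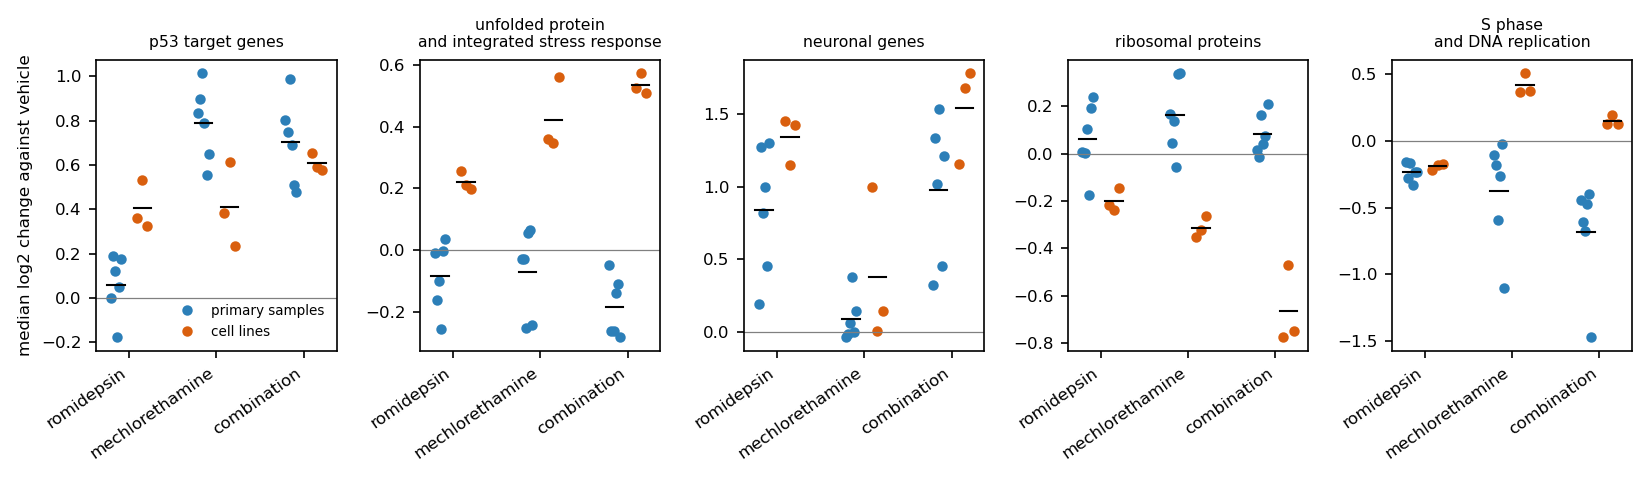
Median log2 change against vehicle of the genes of 5 lists (vertical axis, log2 units) in each of 6 primary cultures (blue) and 3 lines (orange) for each treatment (horizontal axis), with black bars at group means. With mechlorethamine the p53 medians lay between 0.553 and 1.015 in primary cultures and between 0.233 and 0.614 in the lines.

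**Figure D2:**
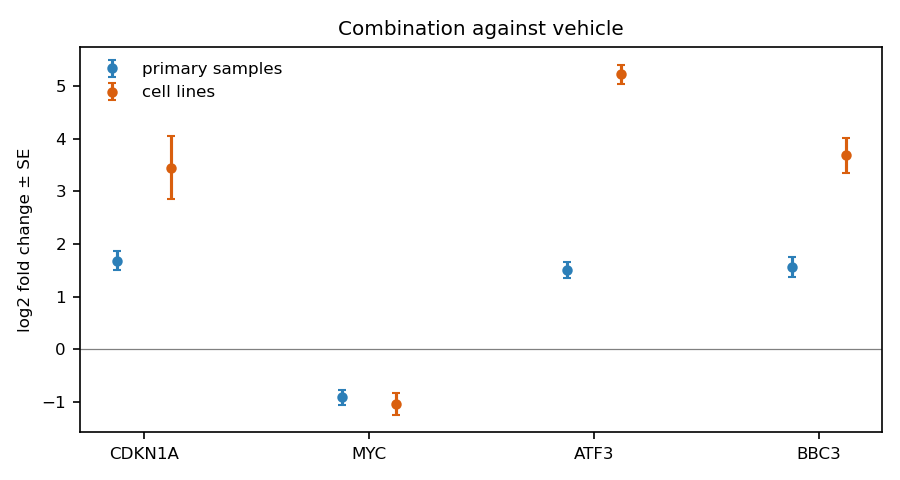
Log2 fold change with the combination against vehicle (vertical axis) of CDKN1A, MYC, ATF3 and BBC3 in primary samples (blue, n = 6 cultures) and lines (orange, n = 3), with bars of 1 SE on either side. ATF3 stood at 1.503 ± 0.15 in primary samples and at 5.22 ± 0.19 in lines.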

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

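The tests of the neuronal list without single libraries, of background reads in every romidepsin library and of single lines were written down after the results they measure had been seen, as were the tests of depth for ribosomal protein genes and for the stress response list alone and that of lists matched on transcript length. The test of background spread evenly over genes was added after the first test of background had come out.

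Among 64 groups of 6 primary libraries or cultures, 6 held a sample far from the others by Dixon's criterion at the 95% level, and chance alone gives about 1 in 20 groups. The T-cell cytokine list had a median log2 change of -1.007 with mechlorethamine in replicate 6, and the S-phase list one of -1.472 with the combination in the same replicate. The interferon-stimulated list had one of -1.376 with the combination in replicate 2. Structural RNA made up 8.742% of counts in the vehicle library of replicate 5, and ribosomal protein genes 7.562% in its romidepsin library. The romidepsin library of replicate 6 had counts for 162 olfactory receptor genes.

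Effects that differed between lines and primary samples, by a test of the difference itself, numbered 1122 genes for romidepsin, 1096 for mechlorethamine and 4398 for the combination. For romidepsin the list medians of the difference were 0.241 for p53 targets, -0.435 for MYC targets, 0.631 for T-helper factors, 0.245 for the stress response, 0.612 for interferon-stimulated genes, 1.773 for drug efflux transporters, -0.202 for glycolysis, -0.339 for ribosomal proteins and 1.657 for monocyte and macrophage markers. For mechlorethamine they were -0.378 for p53 targets, 0.371 for crosslink repair, 0.858 for S phase, 0.507 for G2 and mitosis, 0.159 for MYC targets, -0.169 for T-cell receptor signalling, -0.132 for JAK-STAT and cytokine receptors, 0.333 for NF-kB targets, 0.587 for the stress response, -0.253 for glycolysis and -0.511 for ribosomal proteins. For the combination they were 0.272 for crosslink repair, 0.756 for S phase, 0.768 for G2 and mitosis, 0.491 for core histones, -0.377 for MYC targets, -0.735 for anti-apoptotic genes, -0.742 for T-cell receptor signalling, 0.709 for T-helper factors, 0.174 for NF-kB targets, 0.752 for the stress response, 0.233 for cholesterol biosynthesis, 0.455 for interferon-stimulated genes, 0.935 for drug efflux transporters, -0.432 for glycolysis and -0.848 for ribosomal proteins. With an estimated correlation 5 of these held, T-helper factors, the stress response and drug efflux transporters for romidepsin (adjusted p = 0.0313, 0.00398 and 0.014) and the stress response for mechlorethamine and the combination (adjusted p = 0.000139 and 0.000539).

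Many of these list medians moved by more than 1.5 times, or lost their call, without 1 culture or with another scaling. For romidepsin the T-helper median was 0.371 without Hut78, and the stress response median 0.369 without the romidepsin libraries of SeAx and primary replicate 6. The monocyte and macrophage median was 2.744 and 2.621 without HH and primary replicate 6, and it lost its call without SeAx and primary replicates 4 and 5 (adjusted p = 0.0685, 0.261 and 0.0502). Glycolysis lost its call without SeAx, HH and primary replicates 2 and 5 (adjusted p = 0.0908, 0.325, 0.0833 and 0.0892), with DESeq2's size factors, with library sizes only and without the 2 romidepsin libraries (adjusted p = 0.054, 0.0852 and 0.17).

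For mechlorethamine the p53 median was -0.24 with library sizes only, that of G2 and mitosis 0.191 without primary replicate 6 and that of NF-kB targets 0.209 without SeAx. MYC targets lost their call without HH and primary replicate 6 (adjusted p = 0.23 and 0.205) and stood at 0.272 without primary replicate 5 and 0.297 with library sizes only. T-cell receptor signalling lost its call without HH (adjusted p = 0.0523) and stood at -0.266 without SeAx, -0.103 without primary replicate 5, -0.099 without the 2 romidepsin libraries and -0.04 with library sizes only. JAK-STAT and cytokine receptors stood at 0.005 with library sizes only, where the sign of the median turned, at -0.062 and -0.077 without primary replicates 4 and 5 and at -0.062 without the 2 romidepsin libraries. Glycolysis lost its call without HH and primary replicate 5 and with library sizes only (adjusted p = 0.416, 0.139 and 0.0943).

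For the combination, without HH the medians were -0.38 for T-cell receptor signalling, 0.453 for T-helper factors and 0.808 for interferon-stimulated genes. Without Hut78 they were 0.117 for interferon-stimulated genes and 0.605 for drug efflux transporters, and without primary replicate 5 they were 0.441 for crosslink repair, 0.372 for cholesterol biosynthesis and -0.216 for glycolysis. NF-kB targets stood at 0.024 and 0.357 without SeAx and HH, at 0.419, 0.4 and 0.102 without primary replicates 4, 5 and 6, and at 0.262, 0.293 and 0.28 with DESeq2's size factors, library sizes only and without the 2 romidepsin libraries. Core histones lost their call without SeAx and primary replicate 3 (adjusted p = 0.126 and 0.0532) and stood at 0.279 without primary replicate 6. Cholesterol biosynthesis lost its call without HH and primary replicate 6 (adjusted p = 0.134 and 0.0656) and stood at 0.357 with library sizes only. MYC targets lost their call without Hut78 and primary replicates 3, 4 and 5 (adjusted p = 0.206, 0.0532, 0.0977 and 0.0666), and anti-apoptotic genes without HH, Hut78 and primary replicates 3, 5 and 6 (adjusted p = 0.0857, 0.0741, 0.0532, 0.0764 and 0.107). With DESeq2's size factors, with library sizes only and without the 2 romidepsin libraries, the adjusted p was 0.0541, 0.0759 and 0.0582 for MYC targets and 0.058, 0.0651 and 0.0602 for anti-apoptotic genes.

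Neuronal genes rose with romidepsin, and 2 romidepsin libraries had counts for many olfactory receptor genes. Without those libraries the neuronal median was 1.476 in lines and 0.827 in primary samples, which argues against background reads in these libraries as the whole source, although with an estimated correlation the list then missed the threshold in primary samples (adjusted p = 0.0694) and did not pass in lines with or without the library (adjusted p = 0.138 and 0.155). The romidepsin library of primary replicate 4 was kept, although it had more olfactory receptor counts (648) than either library left out (622 and 471). Per kilobase, olfactory receptor genes gained at least 0.5 of the CPM that neuronal genes gained in 0 of 9 cultures. The medians were 0.0122 and 0.58 and the highest ratio 0.264, which argues against evenly spread background as the source of the neuronal sum's gain. That sum rose by a median of only 0.362 on the log2 scale, so members already expressed with vehicle may carry it. Members near silence were not tested apart. In 7 of 9 cultures the summed olfactory receptor counts rose by at least as much on the log2 scale as the summed neuronal counts, but this decides nothing about background from silent genes, since the sums started at 3.887 to 39.09 and 462.7 to 974.1 CPM with vehicle and a small addition moves the lower one more. An opening of silent genes by romidepsin may give the same values and was not tested apart from background.

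With mechlorethamine, stress response genes rose more in lines than in primary samples, and 11 of 40 p53 targets had a lower and 0 a higher effect in the lines. In 0 of 6 tests with a line left out did either list lose its call at the preset correlation, which argues against a single line as the source at that correlation. With an estimated correlation the stress response list still passed without each line, but the p53 list passed neither in all cultures (adjusted p = 0.174) nor without SeAx, HH and Hut78 (adjusted p = 0.294, 0.285 and 0.368), so a lower p53 response as a list stays open. In thinned counts a share of 0.857 of the called stress response genes (12 of 14) stayed called and the median was 0.576 against 0.587, which argues against low depth for that list, while for p53 targets the share was 0.727 (8 of 11) and the median -0.272 against -0.378, too close to the bounds set for depth to decide. The kind of cell, stimulation, medium and serum differ together between the groups, so a biological difference could not be separated from culture conditions.

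Ribosomal protein genes fell with the combination in lines. As a list they did not pass with an estimated correlation, as given above. Their median of -0.652 lay at percentile 0.45 among 10000 lists of coding genes matched on principal transcript length and expression. This argues against loss of short transcripts as the whole cause, but lists drawn gene by gene lack the correlation among ribosomal protein genes. Such lists also had a low median, -0.39, so a part of the fall may come from that loss. A percentile of 0.05 among lists matched on exon length decides nothing, since exons merged over transcripts (median 3119.5 bases) exceed the principal transcripts (912.5 bases). In thinned counts 69 of 69 genes called lower stayed so and the median was -0.61, which argues against unequal depth alone. These genes are abundant, so their calls were hardly at risk, and thinning does not imitate RNA of poor quality. The higher share of structural RNA in the same libraries may point to RNA of other quality or to dying cells, which no value here decides.

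Other splits of the libraries into groups of the same sizes were tested with pairwise fits, so the real counts differ from those reported. In primary samples the real split alone, 1 of 100, reached its count for romidepsin (3805, highest other 2130) and the combination (4065, highest other 2322). The same held for the combination against mechlorethamine (3576, highest other 2239). For mechlorethamine and for the combination against romidepsin 2 of 100 splits reached the real count (68 and 112, highest other 773 and 528). The higher split of each parted 2 of the 6 cultures and called several times the real count, which points to the structure of the cultures. Among the 32 splits that part every culture, as the real one does, the highest others were 641, 0, 551, 0 and 502 for romidepsin, mechlorethamine, the combination and the combination against romidepsin and mechlorethamine. Only those 32 splits keep the pairing. The real split alone reached its count among them, 1 of 32, the smallest share they allow, so chance is unlikely but not excluded. For non-additivity in primary samples, 32 of 32 swaps gave 0 genes. In lines the splits, 10 for each comparison and 4 for non-additivity, are too few for a share under 0.05, with real counts of 4274, 2108, 5745, 3452, 5287 and 13 and a highest other of 0 for each, and 1 split as large, the real one. For the differences between lines and primary samples, 1 of 84 splits, the real one, was as large for each treatment (1122, 1096 and 4398, highest other 3, 14 and 303). That is the smallest share 84 splits allow, so chance is unlikely but not excluded.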

How the results depend on the processing

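Leaving out the romidepsin libraries of SeAx and primary replicate 6 was chosen after the data had been seen, and the other alternatives were planned. The cause of the changes below was not tested, except that a higher fold threshold lowers the number of calls by construction.

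Of 15 counts of called genes, these moved by more than 1.5 times. Mechlorethamine in primary samples (99) gave 240 with DESeq2, 248 with limma-voom and 170 in a fit of all 36 libraries. The combination against romidepsin (81) gave 186, 152 and 151, and 29 without the romidepsin library of primary replicate 6. Non-additivity in lines (13) gave 59 with DESeq2, 29 with limma-voom, 21 with DESeq2's size factors and 8 with library sizes only. It gave 114 with no filter on low counts and 5 without the romidepsin library of SeAx. Thinned counts gave 2828 for romidepsin in lines (4527), 511 for the difference of the romidepsin effect (1122) and 709 for that of the mechlorethamine effect (1096). The romidepsin difference was 507 without the romidepsin libraries of SeAx and primary replicate 6. A log2 fold change beyond 1 left 764, 46, 1169, 31 and 943 genes in primary samples for romidepsin, mechlorethamine, the combination, and the combination against romidepsin and mechlorethamine, 1571, 356, 3212, 742 and 2018 in lines, and 475, 264 and 1938 for the differences of the romidepsin, mechlorethamine and combination effects.

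Leaving out each culture in turn gave ranges, in primary samples, of 2035 to 3594 for romidepsin, 38 to 150 for mechlorethamine, 23 to 98 for the combination against romidepsin and 2802 to 4222 for the combination against mechlorethamine. In lines they were 2542 to 5202 for romidepsin, 791 to 2498 for mechlorethamine, 1661 to 4041 for the combination against romidepsin, 3369 to 5469 for the combination against mechlorethamine and 7 to 135 for non-additivity. For the differences they were 437 to 1038 for romidepsin and 455 to 953 for mechlorethamine.

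The majority of higher or lower calls turned under other settings too, the fold threshold and the missing block aside. In primary samples it did so in 5, 4, 3, 3 and 2 of 16 settings for romidepsin, mechlorethamine, the combination, and the combination against romidepsin and mechlorethamine. In lines it did so in 3, 6, 4, 5 and 8 of 13 in the same order and in 9 for non-additivity, and in 12, 6 and 6 of 18 for the differences of the romidepsin, mechlorethamine and combination effects. Splits of these counts near even are therefore no sign of a direction.

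Without the culture block that pairs the libraries, counts in primary samples were 150, 0, 420, 0 and 215 for romidepsin, mechlorethamine, the combination, and the combination against romidepsin and mechlorethamine, and 0 for non-additivity. In lines they were 1890, 250, 5290, 1180, 3283 and 0 in the same order, and 1, 0 and 730 for the differences of the romidepsin, mechlorethamine and combination effects. Without the pairing, differences between cultures enter the spread, so a lost call here is not a weaker effect. It ended the calls of 104 of the 241 gene results in the text.

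No list turned its direction by camera, but the median of the JAK-STAT and cytokine receptor list in the difference of the mechlorethamine effect went from -0.132 to 0.005 with library sizes only. Of 156 list calls, 140 were lost with an estimated correlation, 9 with library sizes only and 5 with DESeq2's size factors. Leaving out the romidepsin libraries of SeAx and primary replicate 6 ended 13, and leaving out a culture ended 87 of 855 list calls. No gene result in the text turned its direction, and leaving out a culture ended 15 of their calls. Among the 1035 gene results that the rule named and the text does not print, leaving out a culture ended 369 calls and turned 18, and thinned counts ended 56 and turned 3, so the genes printed were steadier than those left out. The smallest library, the combination of SeAx, had 1841066 counts.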

Other observations

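In primary samples ribosomal protein genes held 5.53% ± 0.863 with vehicle and 6.12% ± 0.873 with the combination (SD, n = 6). Within cultures the share was higher with the combination in 6 of 6 (mean difference 0.584 ± 0.397 percentage points, SD). The exact two-sided sign-flip test gave p = 0.0312 (adjusted p = 0.188 over 24 tests).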
